A study of Mus musculus with 21 samples.

How the data were processed

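Per the labels' protocols, primary isolated mouse cells of the C57BL/6J strain were grown without treatment in DMEM/F12 medium with 10% fetal bovine serum, total RNA was taken with TRNzol reagent, and small RNA libraries followed a BGI protocol. The labels state that the testicular cells were isolated by methods described earlier and that the smooth muscle-like cells came from a supplier. Per the submitters' processing notes, Bowtie2 and the mouse build mm10 were used. Their versions and roles, adapter removal, size selection, the rule for tags that fit more than 1 entry and the version of the miRNA database are not given in the sources used here.

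The deposited table held 61628 entries with 2 values per library, read counts and TPM, both made by the authors. The counts were whole numbers and were used as they stood. The deposited TPM values were counts scaled to 1e6 tags of all classes without a length correction, with a count of 0 written as 0.001, and were read only to learn the total number of tags of each library. That total lay above the summed counts of a library by 0.00128% to 1.265%. Entries were 1556 mature miRNAs with a miRBase name, 17 hairpins, 230 predicted miRNAs, 168 precursors, 58900 piRNAs, 376 other Rfam RNAs, 352 snoRNAs, 13 snRNAs, 10 rRNAs, 2 tRNAs and 1 entry each for intron, exon, intergenic and repeat tags. Of the mature entries, 12 held 0 in all libraries. Each of the 21 libraries was assigned to 1 of 7 cell types, with 3 libraries per type.

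Only the mature entries were tested between cell types. miRNAs with at least 10 counts in at least 3 libraries were kept, which left 846. Counts were scaled with TMM and tested in edgeR 4.0.16 (R 4.3.3) with the robust quasi-likelihood test, all 21 libraries in 1 fit with 1 coefficient per type (14 residual degrees of freedom, common dispersion 0.299). Each of 3 averaged contrasts weighed the types of a group equally: PTM cells against Sertoli, Leydig and germ cells, PTM cells against the 3 smooth muscle types, and the 3 smooth muscle types against Sertoli, Leydig and germ cells. PTM cells were also set against each of the 6 other types. A miRNA was called at a Benjamini-Hochberg adjusted p under 0.05 over the miRNAs tested in a contrast. A miRNA was called enriched in a type when it was called higher, with a log2 fold change of at least 1, in the 6 tests of that type against each other type. Fold changes are given as log2 values with the standard error of the fit. CPM are counts scaled to 1e6 mature tags after TMM, as mean and standard deviation of 3 libraries.

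Lists of miRNAs were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over 18 lists and the 3 averaged contrasts. An estimated correlation and fry were run beside it. The camera test sets the members of a list against all other miRNAs tested, so its direction is relative to them. The fry test takes the members by themselves. The 20 lists, fixed before the data were examined, were miR-143 and miR-145, the striated muscle miRNAs, the smooth muscle dedifferentiation miRNAs, the Dlk1-Dio3 cluster, miR-199 and miR-214, the Hox-linked miRNAs, miR-34b, miR-34c and miR-449, the X-linked testis cluster, the miR-290 cluster, miR-17 and its paralogous clusters, the gonadal somatic miRNAs, miR-132 and miR-212, endothelial miR-126, the haematopoietic miRNAs, epithelial miR-200 and miR-205, the intestinal epithelial miRNAs, miR-122, let-7 and miR-98, miR-29 and the Sfmbt2 repeat cluster. miR-126 and miR-122 had fewer than 3 tested members and were left out of camera. Shares of tag classes and of list members were compared with exact permutation tests of the difference in means, two-sided, over every split of the libraries, with Benjamini-Hochberg adjustment over 15 tests of classes and 15 tests of lists. These tests treat pooled libraries of different types as interchangeable. The smallest p they can give is 0.0045 with 220 splits and 0.00075 with 1330.

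The contrasts, the filter, the tests, the lists, the alternatives to the scaling, filter and test, and the rule for naming miRNAs were set before the data were examined. That rule names the miRNAs called in an averaged contrast and in each of its 3 pairwise tests with at least 50 CPM (10 largest in each direction), the 3 largest in each direction of a pairwise test, the 5 enriched miRNAs with the largest lowest fold change, the 5 most abundant of each type, and the 4 most abundant members of each list. Every mature miRNA printed was named by this rule, except let-7e-5p in the results flagged for a closer look. That miRNA, the further contrasts in which a named miRNA is printed, and the table's predicted and hairpin entries were chosen after their values were seen. The exact tests of classes and of list shares and 6 of the alternatives were also added after the values were seen: tags of all classes as library size, removal of unevenly counted miRNAs, hairpin entries added, libraries thinned to the lowest mature total, removal of 4 libraries with almost no let-7e-5p, and PTM cells against Sertoli and Leydig cells alone. Alternatives set beforehand were RLE scaling, library totals, totals without the 10 most abundant miRNAs, no filter, a filter of 100 counts, DESeq2 1.42.0, limma with a trend, a fit on the compared libraries alone, leaving out each library and the replicate number in the model.

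The main test was tested on simulated data built from the PTM and Sertoli libraries. Of miRNAs changed 2-fold, 5 of 67 (7.46%) were called, of those changed 4-fold 24 of 67 (35.8%), of those changed 8-fold 48 of 66 (72.7%), and of those left unchanged 4 of 646 (0.619%). DESeq2 called 10.4%, 49.3% and 78.8% with 9 unchanged ones, and limma 11.9%, 38.8% and 74.2% with 2 unchanged ones. A list of 28 members changed 4-fold gave an adjusted p of 3.0e-33 in camera, and 0 of 20 unchanged lists passed. Each miRNA was drawn independently and the lists were random. They therefore cannot show how camera behaves on lists whose members move together. With 3 libraries per type, many 2-fold differences between 2 types therefore stay below the threshold.

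Before TMM, 3 counts in a library stood for 5.72 counts per 1e6 mature tags in the shallowest germ cell library and for 0.206 in the deepest library. A fold difference against a group with 0 counts is given as a lower bound from a floor of 3 counts per library after TMM, averaged over the group (0.490 CPM in PTM cells and 0.218 CPM in vascular smooth muscle cells), and against a group with 1 to 3 counts as a ratio with its 95% counting interval. These bounds and intervals cover counting error only. In 30 miRNAs, 28 of them tested, libraries of 1 type lay over 30-fold apart at 50 CPM or more, and every pair of libraries of a type differed by more than sampling noise (chi-squared per degree of freedom 160.6 to 1889). Genomic positions are 1-based, from GENCODE vM21 on GRCm38/mm10, which held the gene of 115 of the 116 named miRNAs.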

Results

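Small RNA was sequenced from 7 types of primary mouse cells: peritubular myoid (PTM) cells of the testis, Sertoli, Leydig and germ cells, and vascular, intestinal and tracheal smooth muscle cells (VSMC, ISMC and TSMC). Each type had 3 libraries (21 in all) of 18.1 to 26.1 M tags (M, 1e6 tags). Mature miRNAs took 0.525 to 0.958 M tags in germ cells and 4.04 to 14.6 M in the other 18 libraries. The labels do not say whether the 3 libraries of a type came from separate animals or cultures. They may be technical replicates, and the p-values then measure only the spread between these samples.

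The first question was how the small RNA classes were divided among the types. Mature miRNAs made up 38.0 ± 7.81% of all tags in PTM cells, 39.4 ± 16.0% in Sertoli cells, 50.5 ± 6.84% in Leydig cells, and 58.7 ± 4.62%, 43.0 ± 3.90% and 38.0 ± 8.19% in vascular, intestinal and tracheal smooth muscle cells (n = 3 each). Germ cells stood apart with 2.93 ± 0.89% mature miRNA tags against 44.6 ± 10.8% in the other 18 libraries. piRNAs, the small RNAs that silence transposons in the male germ line, took 24.3 ± 7.24% of germ cell tags against 1.86 ± 0.54%, and tags of intergenic sequence took 43.9 ± 2.06% against 4.54 ± 1.17%. Each of these 3 differences had a two-sided exact permutation p of 0.00075 over 1330 splits (Benjamini-Hochberg adjusted p = 0.0038 over 15 tests). In the same permutation tests rRNA tags (1.3% and 3.73%, adjusted p = 0.142) and repeat tags (13.4% and 18%, adjusted p = 0.201) were not past the threshold. piRNA tags took 2.50 ± 0.19% in PTM cells and 1.57 ± 0.36% in the 9 smooth muscle libraries (two-sided exact permutation p = 0.0045 over 220 splits, Benjamini-Hochberg adjusted p = 0.017 over the 15 tests). By type they took 1.17%, 1.58% and 1.94% in vascular, intestinal and tracheal cells, and Sertoli cells held 2.44%. No class of 5 was past the threshold between PTM cells and the pooled libraries of the other testicular types (lowest adjusted p = 0.234 in the same permutation tests). This pooled test can miss differences from a single type, such as germ cells.

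**Figure D1:**
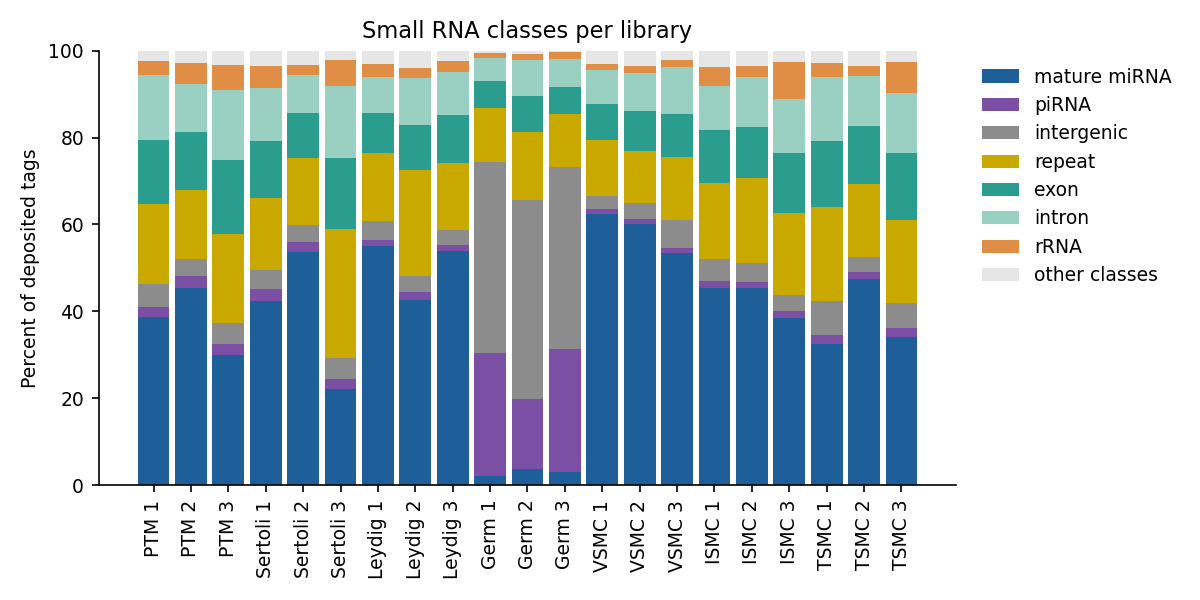
Percent of all deposited tags in each small RNA class, 1 bar per library, with 3 libraries of each cell type. Germ cells hold few mature miRNA tags and many piRNA and intergenic tags.

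To see which types had similar miRNA profiles, libraries were compared over the 846 miRNAs tested. PTM cells were closest to Sertoli cells (mean Spearman correlation 0.872, range 0.844 to 0.895 over library pairs), then to Leydig cells (0.844), and further from tracheal (0.734), intestinal (0.726) and vascular (0.717) smooth muscle cells and from germ cells (0.705). Correlations within a type were 0.896 in Sertoli cells to 0.959 in vascular smooth muscle cells. The 3 smooth muscle types, which per the labels came from a supplier, correlated at 0.908 to 0.933 with each other. The testicular cells were isolated by methods described earlier. The distance between these 2 kinds of cells can follow tissue or source, which cannot be told apart. Leydig cells lay nearer to the smooth muscle types (0.803 to 0.821) than to Sertoli cells (0.749), and Sertoli cells were 0.610 to 0.648 from the smooth muscle types. The first 2 principal components held 50.8% and 21.8% of the variance. By the edgeR quasi-likelihood F test with Benjamini-Hochberg adjustment, 683 of 846 miRNAs differed among the 7 types.

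**Figure D2:**
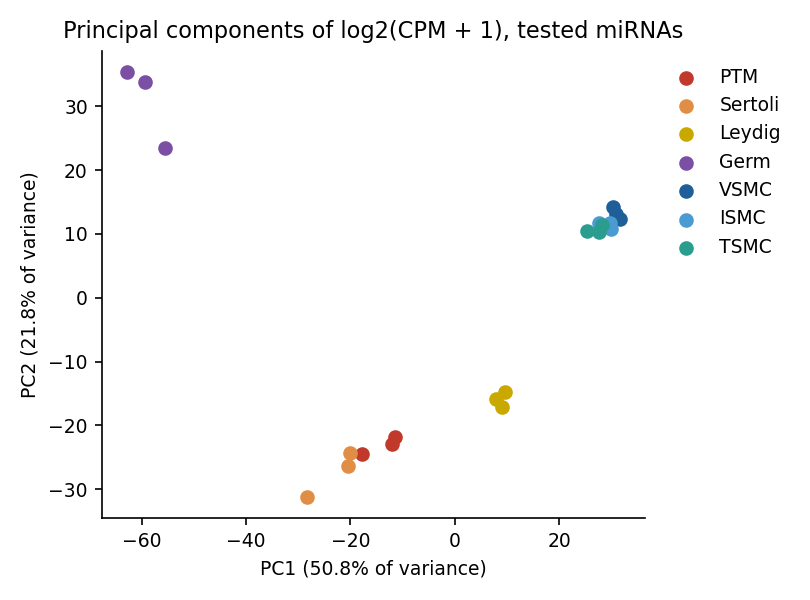
Principal components of log2(CPM + 1) of the mature miRNAs tested, 1 point per library, colored by cell type. PTM libraries lie with Sertoli and Leydig libraries and apart from smooth muscle and germ cell libraries.

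The most abundant miRNAs of PTM cells were let-7c-5p (221400 ± 81668 CPM, 17.3% of mature tags), let-7b-5p (166680 ± 39358 CPM, 13.3%), miR-652-3p (109440 CPM, 9.10%), miR-470-5p (54757 ± 29328 CPM, 4.24%) and let-7a-5p (46689 CPM). let-7c-5p was also first in Leydig cells (20% of mature tags). Germ cells were led by miR-449a-5p (120050 ± 66213 CPM, 20.4%), miR-191-5p (57583 CPM, 10.3%) and miR-92a-3p (47009 CPM), with miR-375-3p at 29301 ± 9545 CPM and miR-34b-3p at 21206 ± 9876 CPM. In vascular smooth muscle cells miR-127-3p, a maternally expressed miRNA of the imprinted Dlk1-Dio3 region, reached 47353 ± 2901 CPM, against 10606 CPM in PTM cells and 913 CPM in Sertoli cells. The let-7 and miR-98 family took 43.5 ± 5.59% of mature tags in PTM cells and 43.7 ± 5.07% in smooth muscle cells, and 8.49 ± 2.59% in germ cells against 44.4 ± 4.2% in the 18 other libraries (two-sided exact permutation p = 0.00075 over 1330 splits, Benjamini-Hochberg adjusted p = 0.0056 over 15 tests).

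The next question was which miRNAs set PTM cells apart from the other testicular cells, taken as the mean of Sertoli, Leydig and germ cells. Of 846 miRNAs, 225 were called, 193 higher and 32 lower in PTM cells (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment; 327 had an unadjusted p under 0.05). miR-150-5p (log2 fold change 1.96 ± 0.31, adjusted p = 0.00022) and miR-126a-3p (2.22 ± 0.40, adjusted p = 0.00054) were the 2 miRNAs with at least 50 CPM that were also called higher against each of the 3 types. Against germ cells their calls were lost in 5 and 14 of 20 alternatives. Of these 2, miR-150 is known from mature lymphocytes and miR-126 from endothelial cells. The muscle miRNA miR-133a-3p (3.12 ± 0.48, adjusted p = 0.00022), miR-470-5p (2.83 ± 0.37, adjusted p = 0.00011), miR-200b-3p (2.19 ± 0.54, adjusted p = 0.0059) and miR-143-3p (1.83 ± 0.45, adjusted p = 0.0057) were higher as well. Sertoli cells alone held more miR-133a-3p (742 CPM) than PTM cells (261 CPM), with uneven counts of 3061, 11531 and 1303 in the Sertoli libraries. The miR-143 and miR-145 share was also larger in Sertoli (3.72% of mature tags) than in PTM cells (2.21%). Between PTM and Sertoli cells, miR-133a-3p and miR-143-3p were not past the threshold. miR-449a-5p (−3.28 ± 0.53, adjusted p = 0.00024), miR-34c-5p (−2.72 ± 0.39, adjusted p = 0.00015) and miR-375-3p (−2.27 ± 0.39, adjusted p = 0.00034) were lower. No miRNA with at least 50 CPM was lower against all 3 types. miR-206-3p (−0.22 ± 0.57), miR-199a-5p (−0.04 ± 0.49), miR-10b-5p (0.19 ± 0.40) and miR-29a-3p (0.21 ± 0.35) were not past the threshold.

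This average leaned on germ cells, on scaling and on the second PTM library, without which 123 miRNAs were called (97 higher, 26 lower). Without germ cells 50 miRNAs were called (43 higher, 7 lower), miR-375-3p turned to 1.3 (adjusted p = 0.022) and miR-143-3p, miR-127-3p, miR-34c-5p and miR-449a-5p were no longer called. The share of called miRNAs that were higher was 85.8% with TMM, 60.0% with RLE scaling and 64.9% with library totals. It was 74.1% with the 10 most abundant miRNAs left out of the totals and 96.9% per tag of all classes. In the same order the median log2 fold change was 0.81, 0.46, 0.54, 0.64 and 1.44. miR-145a-5p (1.49 ± 0.53, adjusted p = 0.042) and miR-202-3p (1.60 ± 0.57, adjusted p = 0.044) lost their calls in 20 and 19 of 27 alternatives.

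**Figure D3:**
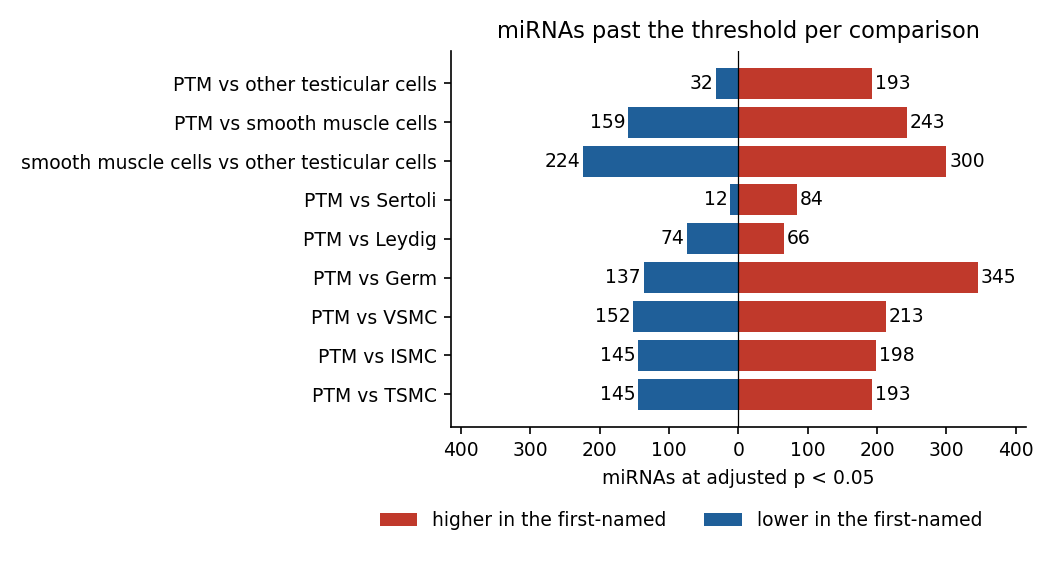
Number of mature miRNAs, of 846 tested, higher (red) or lower (blue) in the first-named cells of each contrast at an adjusted p under 0.05. Of the single types, germ cells differ from PTM cells in the most miRNAs and Sertoli cells in the fewest.

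Among the fixed lists, the Dlk1-Dio3 cluster had 42 of 88 members higher, 0 lower and 46 not past in PTM cells against the other testicular cells (51 higher adjusted over the list alone, median log2 fold change 1.34). Its higher members included miR-127-3p (1.72 ± 0.33), miR-411-5p (1.62 ± 0.35) and miR-433-3p (1.17 ± 0.36). The list passed camera (Benjamini-Hochberg adjusted p = 7.8e-06, adjusted p = 0.307 with an estimated correlation). The average hides a lower level than in Leydig cells. The cluster took 1.24% of mature tags in PTM, 0.122% in Sertoli, 0.345% in germ and 2.98% in Leydig cells. The X-linked testis cluster had 14 of 28 members higher, 0 lower and 14 not past (18 higher adjusted over the list alone, median 1.79, camera adjusted p = 0.0032, adjusted p = 0.589 with an estimated correlation). Leaving out the second PTM library ended this call (camera adjusted p = 0.202). The X-linked share of mature tags was 5.94% in PTM, 6.37% in Sertoli, 8.27% in germ and 0.061% in Leydig cells. By share, PTM cells thus stood above Leydig cells alone. All 5 members of miR-34b, miR-34c and miR-449, miRNAs of meiotic and haploid germ cells, were lower (5 adjusted over the list alone, median −2.69, camera adjusted p = 3.3e-11, adjusted p = 0.0069 with an estimated correlation). miR-17 and its paralogous clusters had 1 higher, 4 lower and 10 not past (1 higher and 7 lower adjusted over the list alone, median −0.79, camera adjusted p = 2.0e-04, adjusted p = 0.186 with an estimated correlation), with miR-20a-5p at −1.51 ± 0.41. The cAMP-responsive miR-132 and miR-212 had 4 of 4 higher (4 adjusted over the list alone, median 1.66, camera adjusted p = 0.023, adjusted p = 0.320 with an estimated correlation), with miR-212-3p at 1.67 ± 0.39. The Sfmbt2 repeat cluster had 1 of 42 higher, 3 lower and 38 not past (1 higher and 2 lower adjusted over the list alone, median −0.63, camera adjusted p = 6.3e-08, adjusted p = 0.132 with an estimated correlation). Its camera result is relative to the other miRNAs, as the median over all miRNAs tested was 0.81. Beside 67 genes on chromosome 2 this list also held genes on other chromosomes. The intestinal epithelial miRNAs had 0 higher, 1 lower (miR-375-3p) and 2 not past (0 and 1 adjusted over the list alone, median −0.56, camera adjusted p = 0.015, adjusted p = 0.186 with an estimated correlation). Per tag of all classes the medians of the Sfmbt2 and intestinal lists turned to 0.11 and 0.22. Without germ cells they turned to 0.54 and 0.32, and the camera calls of both lists, of miR-34b, miR-34c and miR-449, of miR-17 and its paralogous clusters and of miR-132 and miR-212 were lost.

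The other lists were not past camera in this contrast. By fry, miR-143 and miR-145 (adjusted p = 0.011), the striated muscle (0.0036) and dedifferentiation miRNAs (0.012), and let-7 and miR-98 (0.0033) passed upward. The miR-199 and miR-214, Hox-linked, miR-290 and miR-29 lists did not pass fry. miR-143 and miR-145 had 3 of 4 higher, 0 lower and 1 not past (3 adjusted over the list alone, median 1.63). The striated muscle miRNAs had 2 higher, 1 lower (miR-499-5p, −3.24 ± 1.04, lost in 7 of 27 alternatives) and 3 not past (3 higher and 1 lower adjusted over the list alone, median 1.88). The smooth muscle dedifferentiation miRNAs had 3 higher, 0 lower and 7 not past (5 adjusted over the list alone, median 1.06), with miR-31-5p at 1.32 ± 0.42. let-7 and miR-98 had 9 higher, 0 lower and 6 not past (10 adjusted over the list alone, median 1.04, camera adjusted p = 0.057), with let-7b-5p at 1.25 ± 0.35. Without germ cells let-7b-5p and let-7c-5p turned to −0.16 and −0.24 and their calls ended. For miR-199 and miR-214 all 5 were not past (0 adjusted over the list alone), and the median (0.30) and the direction of camera (down) differed in sign. The same held for the Hox-linked miRNAs, with 7 of 7 not past (0 adjusted over the list alone, median 0.19). Without germ cells both lists passed camera downward (medians −1.42 and −0.61). The miR-290 cluster had 7 of 7 not past (0 adjusted over the list alone, median −0.26). The miR-29 family had 1 higher, 0 lower and 4 not past (1 adjusted over the list alone, median −0.10).

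The haematopoietic and the miR-200 and miR-205 lists were not past camera in this contrast, and miR-126 and miR-122 were too few for it. Of the 4 haematopoietic miRNAs, 2 were higher (miR-150-5p and miR-155-5p, the latter 1.65 ± 0.36), 0 lower and 2 not past (2 adjusted over the list alone, median 1.45), with miR-223-3p at 1.25 ± 0.68 and miR-451a at 1.04 ± 0.70. Of the 2 miR-126 arms, 1 was higher (miR-126a-3p) and 1 was not past (2 higher adjusted over the list alone). Of the epithelial miR-200 and miR-205 list, 5 were higher, 0 lower and 5 not past (5 adjusted over the list alone, median 1.59), with miR-200b-3p at 83.0 ± 67.2 CPM in PTM cells, 68.2 ± 51.4 CPM in Sertoli cells and 4.09 ± 1.41 CPM in Leydig cells. The gonadal somatic miRNAs were not past camera either, and 2 were higher, 0 lower and 2 not past (2 adjusted over the list alone, median 0.93). miR-122-5p stood at 1.44 ± 0.88 and was not past the threshold (0 adjusted over the list alone).

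Against Sertoli cells, 96 miRNAs were called, 84 higher and 12 lower in PTM cells (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment; 168 at an unadjusted p under 0.05). Among called miRNAs with at least 50 CPM in the higher type, the largest on the higher side were 3 members of the Dlk1-Dio3 cluster, miR-382-5p (3.97 ± 0.59, adjusted p = 5.8e-05; 158 CPM in PTM and 10.0 CPM in Sertoli cells), miR-411-5p (3.74 ± 0.52) and miR-667-3p (3.69 ± 0.59). The cluster had 66 members higher, 0 lower and 22 not past (74 higher adjusted over the list alone, median 3.10). miR-150-5p (2.0 ± 0.43) and miR-126a-3p (2.44 ± 0.57) were higher. The lower miRNAs included miR-181c-5p (−1.74 ± 0.42, adjusted p = 0.0058), miR-224-5p (−1.60 ± 0.48, adjusted p = 0.030) and miR-338-5p (−1.54 ± 0.49, adjusted p = 0.044). The X-linked testis cluster had 28 of 28 not past (median 0.13), with miR-470-5p at 54757 CPM in PTM cells and 55044 ± 13718 CPM in Sertoli cells. Muscle miRNAs were not past the threshold either, with miR-143-3p at −0.76 ± 0.59 and miR-133a-3p at −1.50 ± 0.65, but leaned lower in PTM cells. Adjusted over the list alone, 1 of 4 members of miR-143 and miR-145 (median −0.95) and 5 of 6 striated muscle miRNAs (median −1.69) were lower and 0 higher. miR-224-5p and miR-338-5p lost their calls in 8 and 12 of 20 alternatives, and miR-181c-5p without the second Sertoli library.

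Against Leydig cells, 140 miRNAs were called, 66 higher and 74 lower in PTM cells (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment; 257 at an unadjusted p under 0.05). Among called miRNAs with at least 50 CPM in the higher type, X-linked miRNAs and a muscle miRNA led the higher side: miR-743a-3p (7.26 ± 1.03), miR-471-3p (7.18 ± 0.87) and miR-133a-3p (7.04 ± 0.84), and miR-470-5p stood at 6.86 ± 0.64 (adjusted p = 3.5e-07; 471 CPM in Leydig cells). The X-linked cluster had 20 members higher, 0 lower and 8 not past (25 higher adjusted over the list alone, median 6.15). miR-143-3p was higher (2.01 ± 0.61, adjusted p = 0.029). miR-1247-5p (−6.71 ± 0.69, adjusted p = 6.6e-07), miR-1247-3p (−6.66 ± 0.86) and miR-218-5p (−3.28 ± 0.55, adjusted p = 0.00025) were lower in PTM cells, and so was the Dlk1-Dio3 cluster, with 0 higher, 44 lower and 44 not past (69 lower adjusted over the list alone, median −1.75). miR-10b-5p was also lower (−1.99 ± 0.51, adjusted p = 0.011). The gene of miR-1247 lies at chromosome 12:110278048-110278129 (GENCODE vM21, GRCm38/mm10) in an exon of Dio3os, and the 2 genes of miR-218 at chromosome 5:48223942-48224051 and chromosome 11:35616816-35616925 in introns of Slit2 and Slit3. Without Leydig library 1, PTM library 2 or PTM library 3 in turn, 89 to 91 miRNAs were called, and more were higher than lower (47 and 42, 47 and 44, 53 and 37). Leaving out single libraries ended the call of miR-143-3p (4 of 20 alternatives). The share of higher miRNAs, 47.1% with TMM, was 60.0% with library totals (median log2 fold changes −0.06 and 0.17).

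Against germ cells, 482 miRNAs were called, 345 higher and 137 lower in PTM cells (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment; 515 at an unadjusted p under 0.05). miR-365-1-5p (5.25 ± 0.71), miR-351-5p (5.17 ± 0.73) and miR-3102-5p (4.88 ± 0.85) were the largest on the higher side among called miRNAs with at least 50 CPM in the higher type, and the abundant let-7c-5p (4.14 ± 0.54, adjusted p = 2.9e-06) and let-7b-5p (4.08 ± 0.52) followed. Of let-7 and miR-98, 13 of 15 members were higher, 0 lower and 2 not past (median 3.33). miR-143-3p was higher by 4.25 ± 0.67. miR-449a-5p (−11.20 ± 0.81, adjusted p = 8.0e-10), miR-375-3p (−9.43 ± 0.58) and miR-34b-3p (−6.64 ± 0.53) were lower, as were miR-20a-5p (−4.27 ± 0.52) and miR-467a-5p (−3.84 ± 0.53). miR-7218-3p, at 669 ± 170 CPM in germ cells, had 0 counts in PTM cells, at least 1366-fold lower. miR-7210-3p and miR-7214-3p also had 0 counts in PTM cells and were at least 133-fold and at least 120-fold lower. miR-468-3p, at 301 ± 155 CPM in germ cells, had 2 counts in the 3 PTM libraries, a ratio of 2773 with a 95% counting interval of 768 to 22901. The Sfmbt2 cluster had 1 higher, 28 lower and 13 not past (1 and 29 adjusted over the list alone, median −2.72), and the Dlk1-Dio3 cluster 58 higher, 0 lower and 30 not past (60 higher adjusted over the list alone, median 2.53).

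In the germ cell contrast the direction of the modest differences depended on scaling. The share of higher miRNAs was 71.6% with TMM, 50.7% with RLE scaling and 50.2% with library totals. It was 58.4% without the 10 most abundant miRNAs and 92.1% per tag of all classes. In the same order the median log2 fold change was 1.79, 0.69, 0.64, 1.04 and 4.09. With all libraries thinned to the lowest mature total, 154 miRNAs were higher and 164 lower. miR-470-5p (1.65 ± 0.51, adjusted p = 0.0090) and miR-126a-3p (1.53 ± 0.55, adjusted p = 0.022) lost their calls in 10 and 14 of 20 alternatives.

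The third question was how PTM cells differ from the smooth muscle cells of other tissues. Of 846 miRNAs, 402 were called, 243 higher and 159 lower in PTM cells than in the mean of the 3 smooth muscle types (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment; 449 at an unadjusted p under 0.05). With at least 50 CPM, 70 miRNAs were higher and 60 were lower against each of the 3 types as well. The smooth muscle cells came from a supplier and the PTM cells did not. Tissue and source therefore cannot be told apart in any of these differences. miR-202-3p, a gonadal somatic miRNA, was higher by 12.06 ± 0.73 (adjusted p = 4.8e-11; 22491 counts in the 3 PTM libraries and 25 in the 9 smooth muscle libraries), miR-470-5p by 12.02 ± 0.47 (adjusted p = 8.8e-15), and miR-743a-3p by 11.54. miR-10b-5p (5.38 ± 0.38), miR-133a-3p (5.70 ± 0.50), miR-212-3p (3.58 ± 0.38) and miR-150-5p (3.75 ± 0.31) were also higher. On the lower side stood miR-668-3p (−5.39 ± 0.74, adjusted p = 2.5e-06), miR-10a-5p (−4.96 ± 0.51, adjusted p = 5.4e-08), miR-431-3p (−4.90 ± 0.62), miR-433-3p (−4.26 ± 0.50) and miR-1983 (−4.03 ± 0.44). miR-206-3p (−3.33 ± 0.70, adjusted p = 0.00044) and miR-31-5p (−2.79 ± 0.54, adjusted p = 0.00017) were lower too. The share of higher miRNAs was 60.4% with TMM, 49.5% without the 10 most abundant miRNAs and 42.1% per tag of all classes. The median log2 fold changes were 0.22, −0.16 and −0.43. With RLE scaling the median was −0.07 and with library totals −0.13.

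The 2 paralogs miR-10a and miR-10b, which lie within the HoxB and HoxD gene clusters, moved in opposite directions. miR-10a-5p stood at 73.8 ± 22.3 CPM in PTM cells and at 4883, 1992 and 1240 CPM in vascular, intestinal and tracheal smooth muscle cells. miR-10b-5p stood at 1346 CPM in PTM cells and at 151, 62.3 and 3.55 CPM in those 3 types. The gene of miR-10a is at chromosome 11:96317165-96317274 (GENCODE vM21, GRCm38/mm10; intergenic), and that of miR-10b at chromosome 2:74726070-74726137 in an intron of Hoxd3. In the mean of the smooth muscle types against the other testicular cells, miR-10a-5p was higher (4.43 ± 0.30) and miR-10b-5p lower (−5.20 ± 0.34).

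The Dlk1-Dio3 cluster had 0 of 88 members higher, 82 lower and 6 not past in PTM cells than in smooth muscle cells (83 lower adjusted over the list alone, median −2.98, camera adjusted p = 1.8e-32 with Benjamini-Hochberg adjustment, adjusted p = 0.0069 with an estimated correlation). The cluster spans 49 genes at chromosome 12:109563692-109747960 (GENCODE vM21, GRCm38/mm10), where miR-668 and miR-382 lie in exons of Mirg. As a share of mature tags it took 1.24 ± 0.16% in PTM cells and 8.90 ± 1.13% in smooth muscle cells (two-sided exact permutation p = 0.0045 over 220 splits, Benjamini-Hochberg adjusted p = 0.014 over 15 tests), and 0.122%, 2.98% and 0.345% in Sertoli, Leydig and germ cells. PTM cells thus held an intermediate level, above Sertoli and germ cells and below Leydig and smooth muscle cells. miR-127-3p was at −2.11 ± 0.40, miR-411-5p at −2.67 and miR-485-5p at −2.76. The lower side held against each type, with 82 lower and 6 not past against vascular (84 adjusted over the list alone, median −3.41), 79 lower and 9 not past against intestinal (82, median −2.82) and 69 lower and 19 not past against tracheal smooth muscle cells (77, median −2.41). Per the labels the smooth muscle cells came from a supplier and the testicular cells were isolated by methods described earlier, so the tissue and the source of the cells cannot be told apart.

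**Figure D4:**
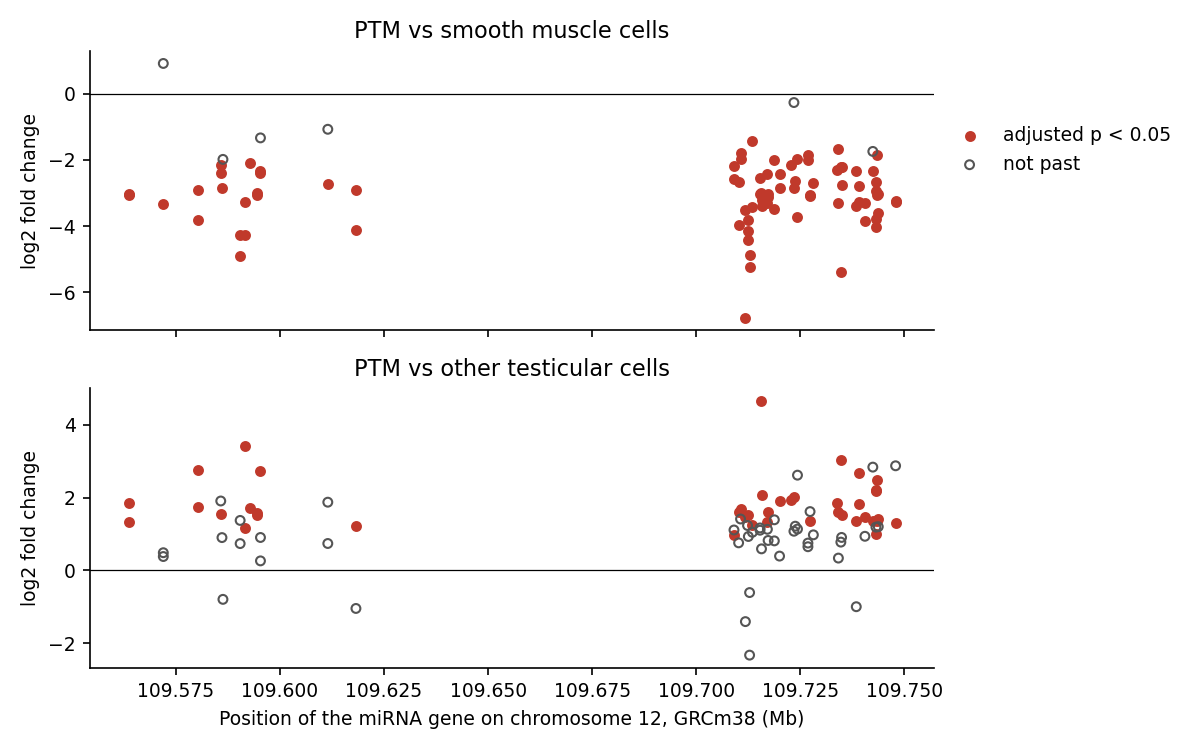
log2 fold change of PTM cells against smooth muscle cells and against the other testicular cells for mature miRNAs of the Dlk1-Dio3 cluster, by position on chromosome 12 (Mb, GRCm38/mm10). Filled points are miRNAs past the threshold, 82 of 88 lower than in smooth muscle cells and 42 of 88 higher than in the other testicular cells. The other testicular cells are the mean of Sertoli, Leydig and germ cells. Leydig cells alone held a larger share of the cluster than PTM cells.

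The X-linked testis cluster had 28 of 28 members higher in PTM cells than in smooth muscle cells (28 adjusted over the list alone, median 9.84, or 9.63 with 3 members at their lower bound, camera adjusted p = 1.3e-22 with Benjamini-Hochberg adjustment, adjusted p = 0.108 with an estimated correlation). It took 5.94 ± 1.84% of mature tags in PTM cells and 0.0038 ± 0.0039% in smooth muscle cells (two-sided exact permutation p = 0.0045 over 220 splits, Benjamini-Hochberg adjusted p = 0.014 over 15 tests), with 6.37 ± 0.79% in Sertoli, 0.061% in Leydig and 8.27 ± 0.98% in germ cells. Its 21 genes lie at chromosome X:66776757-67988451 (GENCODE vM21, GRCm38/mm10). miR-465d-3p (94.9 CPM in PTM cells) had 1 count in the 9 smooth muscle libraries, a ratio of 8694 with a 95% counting interval of 1560 to 343410, and miR-742-3p (87.5 CPM) had 2 counts, a ratio of 4005 with an interval of 1109 to 33066. With 0 counts in vascular smooth muscle cells, miR-465d-3p and miR-742-3p were at least 435-fold and at least 401-fold higher in PTM cells.

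**Figure D5:**
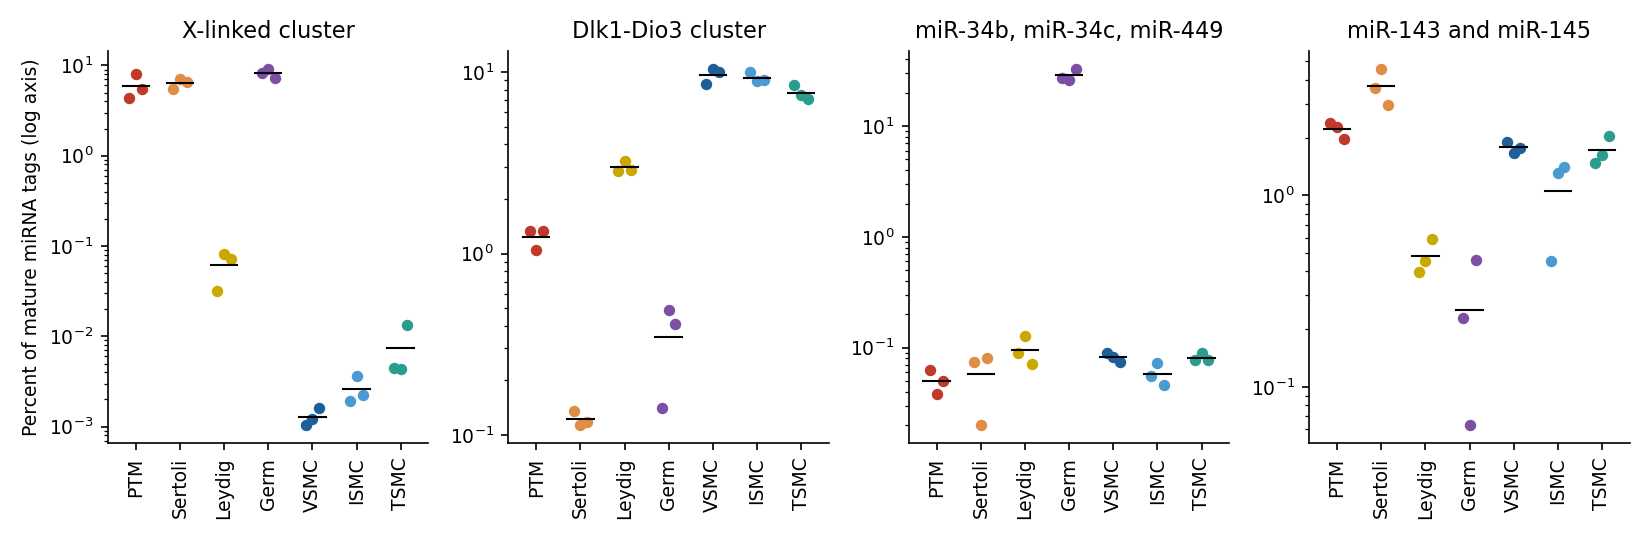
Percent of mature tags (log axis) taken by 4 of the fixed miRNA lists, by cell type, with a point per library and a line at the mean. The X-linked cluster is high in PTM, Sertoli and germ cells and the Dlk1-Dio3 cluster in smooth muscle cells.

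Smooth muscle and muscle lists gave a mixed picture in this contrast. miR-143 and miR-145, which hold smooth muscle cells in the contractile state, had 2 of 4 higher, 0 lower and 2 not past in PTM cells (2 adjusted over the list alone, median 1.15), with miR-145a-5p at 1.87 ± 0.52 (adjusted p = 0.0051) and miR-143-3p at 0.92 ± 0.46 (adjusted p = 0.108; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). They took 2.21 ± 0.22% of mature tags in PTM cells and 1.52 ± 0.46% in smooth muscle cells (two-sided exact permutation p = 0.036 over 220 splits, Benjamini-Hochberg adjusted p = 0.068 over 15 tests). miR-143-3p reached 24897 ± 6769 CPM in PTM cells, 42219 ± 15221 CPM in Sertoli cells and 15655, 9078 and 16112 CPM in vascular, intestinal and tracheal smooth muscle cells. The gene of miR-143 lies at chromosome 18:61649196-61649258 (GENCODE vM21, GRCm38/mm10; intergenic). The striated muscle miRNAs had 2 higher, 1 lower and 3 not past (3 and 1 adjusted over the list alone, median 1.23). The smooth muscle dedifferentiation miRNAs had 3 higher, 2 lower and 5 not past (3 and 2 adjusted over the list alone, median −0.53), with miR-21a-5p at 0.21 ± 0.39, miR-221-3p at −0.72 ± 0.53 and miR-222-3p at −0.61 ± 0.50. None of these 3 lists passed camera. By fry, miR-143 and miR-145 (adjusted p = 0.027) and the striated muscle miRNAs (adjusted p = 0.00020) passed upward. The dedifferentiation miRNAs did not pass fry (adjusted p = 0.778). Per tag of all classes miR-145a-5p lost its call.

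A further 4 lists passed camera with Benjamini-Hochberg adjustment in PTM cells against smooth muscle cells, all upward. The miR-290 cluster of pluripotent cells had 6 of 7 higher, 0 lower and 1 not past (6 adjusted over the list alone, median 3.34, adjusted p = 0.019, adjusted p = 0.342 with an estimated correlation), with miR-292a-3p at 3.34 ± 0.42. Its level was low, at 0.0034% of mature tags in PTM cells and 0.0028% in Sertoli cells. Vascular, intestinal and tracheal cells held 0.00029%, 0.00029% and 0.00087%. miR-17 and its paralogous clusters had 11 higher, 0 lower and 4 not past (12 adjusted over the list alone, median 1.16, adjusted p = 0.029, adjusted p = 0.440 with an estimated correlation), with miR-20a-5p at 2.23 and miR-93-5p at 1.26 ± 0.27. miR-132 and miR-212 had 4 of 4 higher (4 adjusted over the list alone, median 3.41, adjusted p = 0.0062, adjusted p = 0.250 with an estimated correlation). The epithelial list had 9 higher, 0 lower and 1 not past (9 adjusted over the list alone, median 6.26, or 5.97 with 1 member at its bound, adjusted p = 9.6e-06, adjusted p = 0.219 with an estimated correlation), with miR-200b-3p at 7.45 ± 0.60, miR-203-3p at 7.51 ± 0.77 and miR-429-3p at 6.29 ± 0.55. The call of miR-17 and its paralogous clusters was lost in 6 of 24 alternatives.

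The remaining lists did not pass camera here. The Hox-linked miRNAs had 3 higher, 2 lower and 2 not past (4 and 2 adjusted over the list alone, median 1.12). The gonadal somatic miRNAs had 2 higher and 2 lower (2 and 2 adjusted over the list alone, median 3.84), with miR-140-5p at −2.19 ± 0.44. The haematopoietic miRNAs had 3 higher, 0 lower and 1 not past (3 adjusted over the list alone, median 1.61), with miR-155-5p at 1.24 ± 0.37 and miR-223-3p at 1.82 ± 0.66 (lost in 11 of 25 alternatives). The intestinal epithelial miRNAs had 3 of 3 higher (3 adjusted over the list alone, median 1.88), with miR-194-5p at 3.14 ± 0.33. miR-199 and miR-214 had 0 higher, 1 lower and 4 not past (0 adjusted over the list alone, median −0.65). let-7 and miR-98 had 6 higher, 0 lower and 9 not past (6 adjusted over the list alone, median 0.67), and the miR-29 family had 1 higher, 0 lower and 4 not past (0 adjusted over the list alone, median −0.32). miR-34b, miR-34c and miR-449 were 0 higher, 0 lower and 5 not past (0 adjusted over the list alone), with a median of 0.32 and camera pointing down. The Sfmbt2 cluster had 6 higher, 0 lower and 36 not past (1 adjusted over the list alone), with a median of 0.20 and camera pointing down. Of the 2 miR-126 arms both were not past (0 adjusted over the list alone; miR-126a-3p at 0.90 ± 0.42), and miR-122-5p was higher (1 adjusted over the list alone), in counts that lay over 30-fold apart between libraries of a type.

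Against single smooth muscle types, 365 miRNAs were called in vascular (213 higher, 152 lower in PTM cells; 415 at an unadjusted p under 0.05), 343 in intestinal (198 higher, the others lower, 393) and 338 in tracheal cells (193 higher, the others lower, 416), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. miR-470-5p was higher by 13.06 ± 0.81, 12.39 ± 0.80 and 10.61 ± 0.75, and miR-202-3p by 12.15, 12 and 12.03. On the lower side miR-10a-5p stood at −6.05, −4.75 and −4.07, miR-668-3p at −5.09, −5.68 and −5.40, and miR-431-3p at −5.07, −4.85 and −4.77. miR-145a-5p was higher than in intestinal (2.17 ± 0.73, adjusted p = 0.021) and tracheal cells (2.38 ± 0.73, adjusted p = 0.013) and stood at 1.06 against vascular cells (adjusted p = 0.239). miR-126a-3p was higher than in tracheal cells (3.12 ± 0.58, adjusted p = 0.00021), at 0.52 against intestinal and at −0.95 against vascular cells, where it reached 3449 CPM. Per tag of all classes the share of higher miRNAs fell from 58.4%, 57.7% and 57.1% to 31.7%, 40.2% and 45.5%. The median log2 fold changes fell from 0.29, 0.14 and 0.21 to −0.71, −0.45 and −0.18. With library totals the share was 47.7%, 47.5% and 47.0% (medians −0.06, −0.23 and −0.14). Without the 10 most abundant miRNAs it was 45.8% and 44.4% in intestinal and tracheal cells (medians −0.30 and −0.24). With RLE scaling it was 46.1% in tracheal cells (median −0.15).

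The calls against the 3 smooth muscle types overlapped, with 146 miRNAs higher and 110 lower in PTM cells than in each of them, where lists drawn independently would share 11.4 and 4.47, and 20 simulations without group differences gave 0. Those simulations held 0.033 calls per test, so their 0 is no measure of the overlap that shared libraries bring where calls exist. Against the 3 other testicular types, 2 miRNAs were higher and 1 lower in all (2.67 and 0.17 for independent lists, 0 in simulations). The 2 miRNAs higher than in all 3 other testicular types were no excess over the 2.67 of independent lists. The PTM libraries stood in all 3 tests of each overlap. Where an overlap was in excess, part of it may come from these shared libraries.

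To see how the 2 kinds of cells differ apart from PTM cells, the smooth muscle types were set against Sertoli, Leydig and germ cells, and 524 miRNAs were called, 300 higher and 224 lower in smooth muscle cells (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment; 554 at an unadjusted p under 0.05). The Dlk1-Dio3 miRNAs miR-412-5p (6.21), miR-433-3p (5.43 ± 0.32) and miR-127-3p (3.83 ± 0.28, adjusted p = 7.6e-11) were higher, with miR-31-5p (4.12 ± 0.36) and miR-206-3p (3.11 ± 0.43). miR-202-3p (−10.46), miR-470-5p (−9.19 ± 0.41, adjusted p = 8.4e-14), miR-449a-5p (−3.73 ± 0.34) and miR-20a-5p (−3.75 ± 0.29) were lower. Of the muscle miRNAs, miR-143-3p was higher by 0.92 ± 0.34 (adjusted p = 0.025), though below its Sertoli cell level in each smooth muscle type, and miR-133a-3p (−2.58, adjusted p = 9.6e-06) and miR-499-5p (−1.69, adjusted p = 0.023) were lower. The calls of miR-143-3p and miR-499-5p were lost in 2 and 7 of 32 alternatives. Tissue and source of the cells cannot be told apart in this contrast either. The share of higher miRNAs, 57.3%, was 83.3% per tag of all classes. The median log2 fold change, 0.33, was 1.64 per tag of all classes and 0.54 without the 10 most abundant miRNAs.

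In all, 8 lists passed camera with Benjamini-Hochberg adjustment in smooth muscle against the other testicular cells. The Dlk1-Dio3 cluster had 84 higher, 0 lower and 4 not past (84 adjusted over the list alone, median 4.30, adjusted p = 4.4e-42, adjusted p = 0.0029 with an estimated correlation). Lower were the X-linked cluster (0 higher, 25 lower, 3 not past, 25 adjusted over the list alone, median −8.10, or −7.92 with members at their bound, adjusted p = 9.8e-15, adjusted p = 0.132 with an estimated correlation), miR-34b, miR-34c and miR-449 (5 of 5 lower, 5 adjusted over the list alone, median −2.68, adjusted p = 0.0012, adjusted p = 0.183 with an estimated correlation) and the miR-290 cluster (7 of 7 lower, 7 adjusted over the list alone, median −3.52, adjusted p = 0.0012, adjusted p = 0.219 with an estimated correlation). Also lower were miR-17 and its paralogous clusters (0 higher, 13 lower, 2 not past, 13 adjusted over the list alone, median −1.84, adjusted p = 9.6e-06, adjusted p = 0.132 with an estimated correlation) and the epithelial list (0 higher, 9 lower, 1 not past, 9 adjusted over the list alone, median −4.72, or −4.61 with members at their bound, adjusted p = 9.6e-05, adjusted p = 0.255 with an estimated correlation). The intestinal epithelial miRNAs (3 of 3 lower, 3 adjusted over the list alone, median −3.21, adjusted p = 0.0027, adjusted p = 0.132 with an estimated correlation) and the Sfmbt2 cluster (2 higher, 17 lower, 23 not past, 2 and 17 adjusted over the list alone, median −0.68, adjusted p = 0.0095, adjusted p = 0.448 with an estimated correlation) were lower too, the latter turning to a median of 0.73 per tag of all classes.

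Outside those 8, miR-143 and miR-145 had 1 higher, 0 lower and 3 not past in smooth muscle cells (0 adjusted over the list alone, median 0.01), and the striated muscle miRNAs 1 higher, 2 lower and 3 not past (1 and 2 adjusted over the list alone, median −0.90). The dedifferentiation miRNAs had 6 higher, 2 lower and 2 not past (7 and 2 adjusted over the list alone, median 1.68), with miR-222-3p at 1.77. miR-199 and miR-214 had 3 higher, 0 lower and 2 not past (3 adjusted over the list alone, median 0.87), with miR-199a-5p at 1.3. miR-132 and miR-212 had 0 higher and 4 of 4 lower (4 adjusted over the list alone, median −1.72), and the gonadal somatic miRNAs 2 higher and 2 lower (2 and 2 adjusted over the list alone, median −2.91). The Hox-linked miRNAs had 2 higher, 2 lower and 3 not past (2 and 2 adjusted over the list alone), with a median of −0.15 and camera pointing up. let-7 and miR-98 had 5 higher, 2 lower and 8 not past (5 and 2 adjusted over the list alone, median 0.43). The miR-29 family had 1 higher, 1 lower and 3 not past (1 and 1 adjusted over the list alone, median −0.02), and the haematopoietic miRNAs 0 higher, 1 lower and 3 not past (0 and 1 adjusted over the list alone, median −0.46). Of miR-126, 1 arm was higher and 1 not past (1 adjusted over the list alone), and miR-122-5p was not past (0 adjusted over the list alone).

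Few miRNAs were called between the smooth muscle types. With 3 libraries per type many differences stay uncalled, as in the simulated data, where 35.8% of 4-fold changes were called. Single miRNAs differed widely between vascular and tracheal cells. Counts over 3 libraries were 6276 and 78 for miR-10b-5p, 143018 and 4570 for miR-126a-3p and, the other way, 133 and 1563 for miR-338-5p. Vascular against intestinal cells gave 11 calls (0 higher, 11 lower; 113 at an unadjusted p under 0.05), vascular against tracheal cells 28 (10 higher, 18 lower; 186) and intestinal against tracheal cells 8 (7 higher, 1 lower; 79), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

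The last question was which miRNAs marked a single type, and 130 were enriched: 114 in germ cells, 14 in Leydig cells, 1 in PTM cells, 1 in Sertoli cells and 0 in each smooth muscle type (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment in each of 6 pairwise tests). At an unadjusted p under 0.05, vascular, intestinal and tracheal smooth muscle cells had 10, 0 and 5 enriched miRNAs, against 7, 0 and 3 with DESeq2 and 0 with limma after adjustment. Per tag of all classes 46 were enriched, 33 of them in germ cells, and the 14 of Leydig cells became 8 to 19 when single libraries were left out and 5 with thinned libraries. The PTM miRNA was miR-150-5p, at 293 ± 45.3 CPM in PTM cells, 72.4 to 81.7 CPM in the other testicular types and 15.3 to 33.1 CPM in smooth muscle types. Its lowest log2 fold change was 1.85 and its highest adjusted p 0.0022. The Sertoli miRNA was miR-181c-5p (lowest log2 fold change 1.41, highest adjusted p = 0.0075). In Leydig cells miR-1247-5p (1281 ± 453 CPM; lowest log2 fold change 6.71), miR-1247-3p (6.66) and miR-218-5p (2.66) led. In germ cells, of which 81 had at least 50 CPM, miR-449a-5p had a lowest log2 fold change of 11.16. RLE scaling, library totals, DESeq2 and thinning ended the call of miR-150-5p (4 of 34 alternatives, adjusted p up to 0.185), and 8 of 34 ended that of miR-181c-5p (up to 0.758). The gene of miR-150 lies at chromosome 7:45121757-45121821 (GENCODE vM21, GRCm38/mm10; intergenic).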

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

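The tests of the 3 patterns in this part were chosen only after the results were seen, while the tests over splits of the libraries were set before.

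Entries outside the mature miRNAs held abundant tags, and a search of the table for large entries that no test used brought up 3 of them. The predicted miRNA numbered 40 reached 29520 ± 13455 counts per 1e6 mature tags (without TMM, as are all levels in this part) in PTM cells, with 38734 in germ cells, 18592 in Sertoli cells, 8748 in Leydig cells and 4862, 16291 and 19765 in vascular, intestinal and tracheal smooth muscle cells. The predicted miRNA numbered 204 reached 10214 ± 5835 in germ cells, 6.56 in PTM cells, 0.455 in Leydig cells and 0 in the 4 other types. The hairpin entry of miR-328-3p stood at 3682 ± 3972 in PTM cells with counts of 19, 27161 and 48808 in the 3 libraries, and every other type except Sertoli cells (1, 2 and 8 counts) also held libraries with at least 4617 counts beside libraries with at most 22. The cause was not tested, and these 3 entries were in no fold change reported here.

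The X-linked testis cluster stood in PTM cells at the level of Sertoli cells. Germ cell RNA with the makeup of the germ cell libraries was bounded by the miR-34b, miR-34c and miR-449 tags of the PTM libraries. It could bring at most 0.418% of the cluster's tags. PTM cells among the Sertoli cells, bounded by the Dlk1-Dio3 share, could bring at most 11.8% of those in a Sertoli library. Neither of these accounts for the level. Germ cells at stages without miR-34b, miR-34c and miR-449 are not bounded in this way and stay open. Sertoli cells among the PTM cells were tested with 16 other miRNAs high in Sertoli cells. These stood at a median of 55.2% of the Sertoli level over the PTM libraries (49.8% to 65.6%), where 11 X-linked miRNAs stood at 77.4% (71.2% to 167%). Of the 16, 10 lay below the lowest X-linked level, down to 23.9% for miR-206-3p. The 16 were picked from these same data. They include muscle miRNAs that PTM cells may express themselves (miR-133a-3p, miR-143-3p, miR-145a-5p and miR-206-3p). Their median therefore cannot measure a share of Sertoli cells. The gap of 0.79 ± 0.49 log2 units (n = 3) leaves this explanation open, and a share of Sertoli cells in the PTM cultures could bring part of the X-linked tags. Expression of the cluster by PTM cells themselves also stays open and was not tested. The X-linked share was largest in library 2 of both PTM (7.96%) and Sertoli cells (7.04%). A link between libraries of the same number was not tested.

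The Dlk1-Dio3 cluster was lower in PTM cells than in smooth muscle cells. For scaling of the libraries, the median log2 fold change closest to 0 over the 4 other scalings was −3.28, so scaling does not account for it. For source of the cells, 0 kinds of cells (testicular, smooth muscle) held both sources, so the tissue and the source cannot be told apart. The cluster may differ by tissue, by the passage of the purchased cells or by their isolation.

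let-7e-5p was counted 1 or 2 times in 4 libraries (1 Sertoli, 1 vascular and 2 tracheal smooth muscle libraries), while other libraries of those types held it at 12403 counts per 1e6 mature tags or more. An entry lost when the table was put together was tested with the tags that the total holds and no entry does: in the 4 libraries these reached 91.8%, 99.8%, 132% and 172% of the let-7e-5p level of the other replicates. The 4 libraries held 26500 such tags per 1e6 mature tags on average and the 17 others 7269 (two-sided exact permutation p = 0.00167 over 5985 splits), though 2 of the others lay at or above the lowest of the 4 (21328). This is consistent with an entry lost in the table, and let-7e-5p values are likely not usable in those libraries, where the let-7 share would then be too low.

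Except for the number of list calls, splits of the libraries into groups that ignore the cell types gave fewer calls than the real groups. Among 100 labelings, the real one included, as many calls as the real one arose in 1 for PTM against the other testicular cells (225 real, 214 at most in another), for PTM against smooth muscle cells (402 and 111), for smooth muscle against the other testicular cells (524 and 291), for enriched miRNAs (130 and 0) and for differences among the 7 types (683 and 164). For the number of list calls, 14 of 100 labelings gave as many as the real 21 (26 at most in another), so that number is no larger than splits that ignore the types can give. For each pairwise contrast of PTM cells the real split, 1 of 10, gave the most calls, with 96 against 2 for Sertoli cells and 140, 482, 365, 343 and 338 against 0 for Leydig, germ, vascular, intestinal and tracheal cells, and 10 splits are too few for a share under 0.05.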

How the results depend on the processing

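The tests with tags of all classes, thinned libraries, hairpin entries, no unevenly counted miRNAs, no 4 libraries with let-7e-5p at 1 or 2 counts and no germ cells were chosen only after the results were seen, and the other tests were set before.

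Of 185 values for named miRNAs, 174 kept their call or its absence with RLE scaling, 173 with library totals, 172 with DESeq2, 181 with limma and 166 with tags of all classes. The number of enriched miRNAs moved with these settings. In PTM cells it was 0 with RLE, 0 with DESeq2, 2 without the 10 most abundant miRNAs and 2 with limma. In Sertoli cells it was 2 with RLE, 4 with DESeq2 and 2 with limma. It was 0 there with library totals, without the 10 most abundant miRNAs and with thinned libraries. In Leydig cells it was 9 with RLE. A filter of 100 counts gave 310 calls for PTM against germ cells, 431 for differences among the 7 types and 8 enriched in Leydig cells, and DESeq2 gave 217 for PTM against Leydig cells. With tags of all classes PTM against the other testicular cells gave 425 calls, with 46 enriched miRNAs in all, 33 in germ cells and 2 in Sertoli cells, and 3 list medians turned in sign: intestinal miRNAs 0.22 and the Sfmbt2 cluster 0.11 for PTM against the other testicular cells, and the Sfmbt2 cluster 0.73 for smooth muscle against those cells.

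Thinned to the lowest mature total, PTM cells gave 110 calls against the other testicular cells, 54 against Sertoli, 85 against Leydig, 318 against germ, 212 against vascular, 199 against intestinal and 199 against tracheal cells, with 5 enriched in Leydig cells. Lower depth thus removes calls, and the differences in depth between types may shape their counts of calls. Without the 4 libraries with let-7e-5p at 1 or 2 counts, PTM against tracheal cells gave 154 calls and Leydig cells 3 enriched miRNAs, but this leaves 1 tracheal library, for which the other types supply the spread. With only the libraries compared in the fit, PTM against the other testicular cells gave 125. Without germ cells that contrast gave 50 calls, and miR-449a-5p (0.68), miR-375-3p (1.3), let-7b-5p (−0.16), let-7c-5p (−0.24) and the medians of miR-199 and miR-214 (−1.42), the Hox-linked miRNAs (−0.61), the intestinal miRNAs (0.32) and the Sfmbt2 cluster (0.54) turned in sign. List calls, 21 with a preset correlation (7, 6 and 8), were 3 with an estimated correlation (1, 1 and 1) and 38 with fry (14, 11 and 13).

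Leaving out single libraries gave 123 to 273 calls for PTM against the other testicular cells, 89 to 111 for PTM against Leydig cells, 1 to 2 enriched miRNAs in PTM cells, 1 to 2 in Sertoli cells and 8 to 19 in Leydig cells. On average over all types, the replicate numbers did not pair libraries. The mean residual correlation was 0.0048 over 63 pairs with the same number (range −0.283 to 0.357) and −0.0026 over the others. A pairing between single types, such as PTM and Sertoli cells, was not tested and could be hidden in this mean. The X-linked share was highest in library 2 of both types (4.38%, 7.96% and 5.47% in PTM, 5.49%, 7.04% and 6.58% in Sertoli libraries). So was the share of the epithelial list (0.0397% and 0.0360% in library 2). The miR-29 family ran the other way (0.548%, 0.520% and 0.941%, against 0.904%, 1.03% and 0.405%). With 3 libraries per type, such orders cannot show whether libraries were paired. With the number as a replicate block PTM against the other testicular cells gave 212 calls, against smooth muscle cells 380, and no count moved by more than 1.5 times.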

Other observations

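The tests of class shares and of list shares printed in this part were chosen only after the results were seen.

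miR-351-5p was abundant in PTM cells (5444 ± 1350 CPM) and lower in germ cells (152 ± 162 CPM) and in vascular, intestinal and tracheal smooth muscle cells (205, 215 and 132 CPM), each past the threshold of edgeR's quasi-likelihood test. In Sertoli cells (1948 ± 1568 CPM) and Leydig cells (1597 ± 419 CPM) the differences were not past it (Benjamini-Hochberg adjusted p = 0.162 and 0.056), though they were in 3 and 9 of 20 alternatives. miR-133a-3p, known from striated muscle, stood at 261 ± 11.9 CPM in PTM cells and 742 ± 667 CPM in Sertoli cells, and at 1.97 CPM in Leydig, 18.8 CPM in germ and 3.29 to 8.48 CPM in smooth muscle cells. miR-206-3p, a second muscle miRNA, ran the other way, with 70.4 ± 49.8 CPM in PTM cells and 747, 583 and 813 CPM in vascular, intestinal and tracheal smooth muscle cells.

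The share of the X-linked cluster was higher in germ cells (8.27 ± 0.98% of mature tags) than in the 18 other libraries (2.06 ± 3.06%; two-sided exact permutation p = 0.0015 over 1330 splits, Benjamini-Hochberg adjusted p = 0.0075 over 15 tests). miR-34b, miR-34c and miR-449 took 28.6 ± 3.85% of mature tags in germ cells and 0.071 ± 0.024% elsewhere (p = 0.00075 in the same permutation test, adjusted p = 0.0056). Against the pooled libraries of the other testicular types, the same permutation test was not past the threshold for PTM cells. This held for the X-linked cluster (5.94% and 4.90 ± 3.77%, adjusted p = 0.766) and the Dlk1-Dio3 cluster (1.24% and 1.15 ± 1.39%, adjusted p = 0.945). Such a pooled test cannot separate a type whose level lies between the others. The Dlk1-Dio3 share was 1.05% to 1.33% in PTM, 0.113% to 0.135% in Sertoli, 0.142% to 0.487% in germ and 2.84% to 3.22% in Leydig libraries. Of the somatic testicular cells, Leydig cells had the highest Dlk1-Dio3 share and the lowest X-linked share.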
